A study of Homo sapiens with 27 samples.

How the data were processed

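The data are 27 Agilent arrays of HepG2 cells exposed for 48 h to 1 of 9 hydrocarbons, 3 arrays per compound, with compound RNA in Cy5 and DMSO RNA in Cy3 on every array per the labels. The labels give neither doses nor dates, and do not say whether arrays of a compound are separate cultures or share DMSO RNA. As deposited, the scanner output holds intensity values of each spot and its local background in both dyes, as pixel means, medians and SDs that were neither normalised nor background-subtracted. The percent of saturated pixels of each spot is also given, per the file headers. The authors also deposited log2 ratios of compound over DMSO, normalised by them in a way the labels do not state and centred near 0 per array. Of the 27 columns of the authors' values, 20 could be tied to spots and were used as an alternative, and 7 matched no spot order and were left out (3MC array 3, NP array 1, CHR array 2, BA array 3 and all of IND).

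All values were computed from the scanner output with R 4.3.3 and limma 3.58.1, after reading with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and drawn with matplotlib 3.10.9. Control spots and spots marked bad (flag -75 or lower) were left out. Spots marked as not found were kept (22457 to 24625 of 41675 per DBA array, 11284 to 14333 with 3MC or NP, 287 to 4730 with others). Background was corrected with normexp at an offset of 50, each array was normalised with loess, and no scaling was applied between arrays. Spots of a probe were averaged. A probe was tested if it stood over 2 background SDs above background in a channel on at least 2 of 3 arrays of a compound. Probes were named through transcript accession, symbol or an older symbol that fits 1 gene only, which named 26427 of 41000 probes on the shared platform and 26789 of 41000 on that of IND. The probe with the highest mean intensity over arrays stood for its gene, and unnamed probes were left out. The number of arrays limits the precision. Where a channel was saturated on all arrays or DMSO did not stand above background, the change is given as a lower bound. Differences between compounds that rest on such spots are given as bounds, as approximate values or not at all.

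The model had 1 mean per compound, fitted to the 24 arrays of the shared platform together and to IND alone. Each compound was tested against DMSO as the mean log2 ratio against 0, and compounds were compared by contrasts and by limma's F test. Tests were 2-sided and adjusted by Benjamini and Hochberg over genes, and a gene passed at an adjusted p under 0.05 and 1.5-fold. For 7 AHR targets all pairs of compounds were tested, adjusted over pairs and genes, and passed at the adjusted p alone. For 23 gene lists camera ran at a preset correlation of 0.01, adjusted over 345 tests, with an estimated correlation and fry beside it. The groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. That rule takes, per compound, the 5 highest and 5 lowest ratios among genes that passed, stood well above background and moved the same way on all arrays, 10 and 10 for the larger compounds minus NP and PH, 3 and 3 for each pair, members of the AHR list, and up to 4 members of each list that passed. A gene named in 1 comparison could be given in another. Some genes that this rule would name are not reported here.

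The alternatives were other background corrections, median centring, quantile scaling between arrays, other filters, the mean of a gene's probes, array weights, a replicate block, the authors' values, other thresholds, separate fits, and leaving out each array in turn. Comparisons within the file layouts, blocks for layout or DMSO set, and leaving out BA array 1 throughout were chosen after seeing the data. Array numbers did not pair arrays across compounds (mean correlation of residuals 0.00309), so no pairing was used. The model and camera were tested on simulated log ratios with 200 changed genes in each of 15 comparisons. There 94% to 100% of 2-fold changes and at least 99% of 4-fold changes were recovered, and at most 2 unchanged genes passed. Camera found the shifted list in 15 of 15 runs. Changes were put in after background correction, normalisation and choice of probe, so losses at dim or saturated spots were not tested. Gene positions are those of the GRCh38 annotation.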

Results

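The study measured messenger RNA in HepG2 cells, a human liver cancer line that keeps many functions of hepatocytes, after 48 h with 1 of 9 polycyclic aromatic hydrocarbons. These compounds of fused aromatic rings form when organic matter burns incompletely. They were naphthalene (NP), phenanthrene (PH), benzo[a]anthracene (BA), chrysene (CHR), 3-methylcholanthrene (3MC), benzo[a]pyrene (BaP), indeno[1,2,3-c,d]pyrene (IND), benzo[k]fluoranthene (BF) and dibenzo[a,h]anthracene (DBA). Each compound had 3 arrays with both dyes, 27 in all, with RNA of treated cells in the Cy5 channel and RNA of cells given the solvent DMSO in the Cy3 channel. The dyes were never exchanged, so a dye bias of a gene stays in its ratio to DMSO. It would cancel in a difference between compounds if it were alike on their arrays, which was not tested. Doses are not given, so compounds are compared as they were applied and their doses may differ. IND was on a platform of its own, with 14376 genes tested, and the other 8 compounds shared a platform of 24 arrays, with 17269 genes.

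The median Cy5 signal per array was 70.0 to 164 intensity units on the DBA, 3MC and NP arrays, whose scanner output also had a layout of its own, and 341 to 1535 on the others. Between 60.7% and 98.1% of the probe spots of an array stood above background in Cy5. The number of arrays limits the precision. Across genes, log2 ratios of arrays of the same compound correlated at 0.905 or more, except for BA, whose array 1 correlated at 0.18 and 0.13 with its arrays 2 and 3. Genes are not independent replicates. The DMSO channel itself was clustered and cut into 3 sets of arrays, a number that was imposed. These were BaP with PH, DBA with 3MC and NP, and CHR with BA, BF and IND. Spearman correlations across probes were 0.96 to 0.99, 0.93 to 0.99 and 0.93 to 0.99 within these sets, and 0.86 to 0.96 between the first and the last. The set of DBA, 3MC and NP had 0.60 to 0.75 with the others. No clear gap parts the first set from the last. BaP with CHR had a mean of 0.945, and CHR with IND, of the same set, 0.944. Values against DMSO are mean log2 ratios ± SD (n = 3). A gene is said to rise or fall where limma gave an adjusted p under 0.05 with a change of at least 1.5-fold. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, adjusted over 345 tests. The test called 121 of them, and 0 with an estimated correlation, so that each p from all arrays is followed by the other. Without BA array 1, a setting chosen after seeing the data, 64 passed with an estimated correlation, so the second p depends on this array. The numbers of list members that rose or fell were the same when adjusted over the list alone, except where both are given. Whether the 3 arrays of a compound are separate cultures is not stated, so these tests measure the spread between these arrays, which may be technical.

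**Figure D1:**
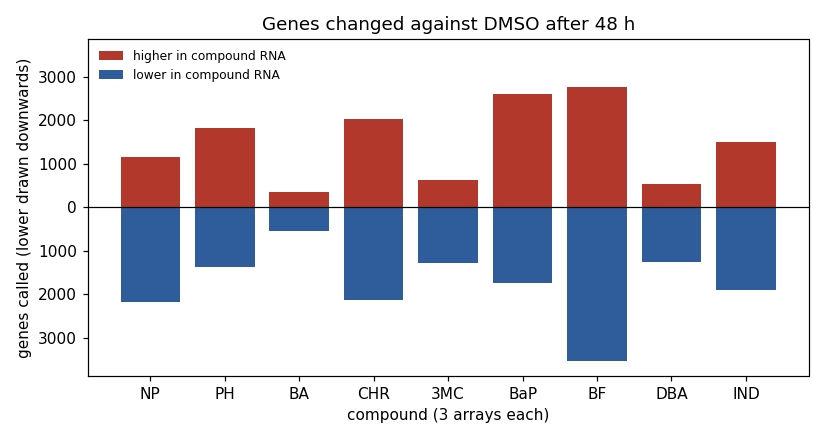
Number of genes that rose (drawn upwards) or fell (drawn downwards) against DMSO for each compound, 3 arrays each, at an adjusted p under 0.05 and 1.5-fold. BF had 2770 and 3518, and BA 353 and 536.

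Against DMSO, BaP raised CYP1A1, a cytochrome P450 that oxidises these compounds and is induced through the aryl hydrocarbon receptor (AHR), by 5.70 ± 0.12. IGFBP3, which binds insulin-like growth factors, rose by 4.76 ± 0.13, ZG16B by 4.64 ± 0.10, PROCR, the receptor of protein C, by 4.48 ± 0.02 and TREM2 by 4.47 ± 0.08. The lowest ratios were in the mitotic kinase PBK (-4.22 ± 0.05), the kinetochore gene NDC80 (-4.21 ± 0.17), GPC6 (-3.83 ± 0.10), the kinesin KIF15 (-3.82 ± 0.0023) and the glutathione transferase GSTA2 (-3.81 ± 0.05). In all, 2605 genes rose and 1733 fell, or 3550 higher and 1329 lower with median centring in place of loess. Among targets of the tumour suppressor p53, 27 of 30 genes rose and 0 fell (adjusted p 2.21e-10, and adjusted p = 0.280 with an estimated correlation). The cell cycle inhibitor CDKN1A rose at least 20.7-fold, with Cy5 saturated on all 3 arrays, TP53I3 by 4.06 ± 0.01 and PHLDA3 by 2.71 ± 0.15. With BaP, 29 of 30 G2 and mitosis genes fell and 0 rose (adjusted p 1.28e-23, and adjusted p = 0.189 with an estimated correlation), with TOP2A at -3.73 ± 0.08, TTK at -3.68 ± 0.25 and CDK1 at -3.68 ± 0.03. With BaP, 23 of 27 DNA replication genes fell and 1 rose (adjusted p 8.41e-11, and adjusted p = 0.257 with an estimated correlation), with RRM2 at -2.67 ± 0.05 and MCM2 at -2.09 ± 0.01. With BaP, 9 of 20 DNA repair genes fell and 4 rose (adjusted p 0.0308, and adjusted p = 0.257 with an estimated correlation), with BLM at -2.87 ± 0.06 and ERCC1 at 1.65 ± 0.07. Histone genes went the other way, as 13 of 15 genes rose and 1 fell (adjusted p 1.26e-04, and adjusted p = 0.284 with an estimated correlation), with H1-2 at 2.57 ± 0.03. Of genes for proteins that hepatocytes secrete, 16 of 25 genes fell and 1 rose (adjusted p 3.60e-06, and adjusted p = 0.254 with an estimated correlation), with haptoglobin (HP) at -2.57 ± 0.10 and APOH at -2.12 ± 0.09. With BaP, 10 of 22 cholesterol synthesis genes fell and 0 rose (adjusted p 2.52e-04, and adjusted p = 0.579 with an estimated correlation). With BaP, 8 of 14 fatty acid synthesis genes fell and 0 rose (adjusted p 0.00143, and adjusted p = 0.560 with an estimated correlation), with SCD at -2.27 ± 0.12. With BaP, 8 of 18 interferon response genes rose and 0 fell (adjusted p 0.0333, and adjusted p = 0.189 with an estimated correlation), with OAS1 at 2.99 ± 0.14. With BaP, 4 of 12 heat shock genes rose and 1 fell (adjusted p 0.0124, and adjusted p = 0.223 with an estimated correlation), with HSPB1 at 2.29 ± 0.11.

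CHR raised CYP1A1 by 5.81 ± 0.45, with Cy5 saturated on 2 of 3 arrays. PROCR rose by 4.42 ± 0.17, CDKN1A by 4.32 ± 0.24 with saturation on 2 arrays, and ZNF385A by 4.10 ± 0.04. Among the lowest ratios were those of GPC6 (-4.45 ± 0.25), LRMDA (-3.32 ± 0.16), NBEA (-3.08 ± 0.10) and SHANK2 (-2.72 ± 0.24). In all, 2027 genes rose and 2127 fell. With CHR, 28 of 30 p53 targets rose and 0 fell (adjusted p 5.29e-14, and adjusted p = 0.218 with an estimated correlation), with TP53I3 at 4.06 ± 0.16 and the death receptor FAS at 3.15 ± 0.19. With CHR, 10 of 17 AHR targets rose and 1 fell (adjusted p 0.0136, and adjusted p = 0.476 with an estimated correlation), with ALDH3A1 at 3.33 ± 0.28. Of targets of NRF2, which drives genes against oxidative stress, 14 of 23 genes rose and 1 fell (adjusted p 1.11e-04, and adjusted p = 0.413 with an estimated correlation), with AKR1B10 at 2.38 ± 0.14 and SRXN1 at 2.23 ± 0.04. With CHR, 8 of 12 heat shock genes rose and 0 fell (adjusted p 7.35e-05, and adjusted p = 0.141 with an estimated correlation), with HSPB1 at 2.28 ± 0.03 and DNAJA1 at 1.05 ± 0.02. With CHR, 6 of 9 genes of the metallothionein list rose and 1 fell (adjusted p 0.0131, and adjusted p = 0.223 with an estimated correlation), with MT2A at least 7.58-fold higher and MT1F at -2.18 ± 0.23. With CHR, 7 of 15 histone genes rose and 0 fell (adjusted p 0.00486, and adjusted p = 0.451 with an estimated correlation), with H1-2 at 2.07 ± 0.17. With CHR, 27 of 30 G2 and mitosis genes fell and 1 rose (adjusted p 1.61e-11, and adjusted p = 0.284 with an estimated correlation), with PLK1 at -2.22 ± 0.11 and BIRC5 at -1.94 ± 0.09. With CHR, 16 of 27 DNA replication genes fell and 2 rose (adjusted p 6.54e-05, and adjusted p = 0.509 with an estimated correlation), with MCM2 at -1.79 ± 0.02 but PCNA, the sliding clamp of DNA polymerases, at 2.38 ± 0.10. With CHR, 14 of 25 secreted protein genes fell and 3 rose (adjusted p 0.00688, and adjusted p = 0.511 with an estimated correlation), with APOC3 at -1.93 ± 0.04. With CHR, 9 of 14 fatty acid synthesis genes fell and 0 rose (adjusted p 0.0124, and adjusted p = 0.635 with an estimated correlation), with ELOVL6 at -1.76 ± 0.09.

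BF raised CYP1A1 at least 75.0-fold, with Cy5 saturated on all 3 arrays. The transporter SLC16A6 rose by 5.23 ± 0.13, the cytokine IL11 by 5.07 ± 0.07, AGR2 by 4.96 ± 0.02, RGS10 by 4.78 ± 0.04 and SLC37A2 by 4.76 ± 0.08. Among the lowest ratios were those of the lysosomal protease CTSD (-4.65 ± 0.13), fatty acid synthase (FASN, -4.43 ± 0.11), the growth factor receptor FGFR4 (-4.33 ± 0.16) and GPC6 (-4.31 ± 0.08). In all, 2770 genes rose and 3518 fell, or 4245 higher and 3222 lower with median centring. With BF, 13 of 17 AHR targets rose and 0 fell (adjusted p 1.74e-05, and adjusted p = 0.223 with an estimated correlation). With BF, 15 of 23 NRF2 targets rose and 1 fell (adjusted p 6.57e-05, and adjusted p = 0.386 with an estimated correlation), with AKR1B10 at 3.40 ± 0.10 and SRXN1 at 3.31 ± 0.06. With BF, 18 of 22 cholesterol synthesis genes fell and 0 rose (adjusted p 9.24e-06, and adjusted p = 0.509 with an estimated correlation), with MVD at -3.23 ± 0.27 and HMGCS1 at -2.31 ± 0.09. With BF, 12 of 14 fatty acid synthesis genes fell and 0 rose (adjusted p 2.16e-04, and adjusted p = 0.466 with an estimated correlation), with SCD at -3.26 ± 0.05. With BF, 22 of 25 secreted protein genes fell and 0 rose (adjusted p 1.53e-09, and adjusted p = 0.189 with an estimated correlation), with alpha-fetoprotein (AFP) at -2.97 ± 0.11 and HP at -2.96 ± 0.10. With BF, 7 of 15 hepatocyte transcription factors fell and 0 rose (adjusted p 0.0334, and adjusted p = 0.466 with an estimated correlation), with CEBPA at -2.46 ± 0.09. With BF, 17 of 30 p53 targets rose and 3 fell (adjusted p 0.00293, and adjusted p = 0.635 with an estimated correlation), with FAS at 2.41 ± 0.09 and PLK3 at 2.29 ± 0.04. CDKN1A rose at least 5.51-fold on the probe used and had -0.33 on another. With BF, 29 of 30 G2 and mitosis genes fell and 0 rose (adjusted p 2.66e-12, and adjusted p = 0.280 with an estimated correlation), with AURKB at -3.59 ± 0.02. With BF, 24 of 27 DNA replication genes fell and 0 rose (adjusted p 2.32e-08, and adjusted p = 0.318 with an estimated correlation), with E2F1 at -2.81 ± 0.09. With BF, 9 of 20 DNA repair genes fell and 2 rose (adjusted p 0.0291, and adjusted p = 0.254 with an estimated correlation). With BF, 12 of 15 histone genes rose and 1 fell (adjusted p 2.28e-05, and adjusted p = 0.254 with an estimated correlation), with H1-2 at 3.96 ± 0.07. With BF, 7 of 12 heat shock genes rose and 0 fell (adjusted p 9.75e-04, and adjusted p = 0.189 with an estimated correlation), with HSPB1 at 1.97 ± 0.04. With BF, 6 of 9 genes of the metallothionein list rose and 1 fell (adjusted p 0.00523, and adjusted p = 0.189 with an estimated correlation), with MT2A at least 9.38-fold higher. The DMSO channel of 864 genes, CTSD among them, differed at least 4-fold between the CHR and BA arrays and the BaP and PH arrays. Over these genes the median BF ratio was 1.05 toward the BaP and PH level.

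IND raised CYP1A1 at least 71.4-fold, with Cy5 saturated on all 3 arrays. AGR2 rose by 4.21 ± 0.24, GPAT3, an enzyme of triglyceride synthesis, by 4.05 ± 0.06, IGFBP1 by 3.67 ± 0.11, NKAIN1 by 3.64 ± 0.31 and TIMP1, an inhibitor of matrix proteases, by 3.30 ± 0.07. Among the lowest ratios were those of AFP (-2.96 ± 0.07), ACSM2B (-2.91 ± 0.16), APOC3 (-2.79 ± 0.02) and HMGCS1 (-2.73 ± 0.01). In all, 1507 genes rose and 1896 fell. With IND, 13 of 16 AHR targets rose and 0 fell (adjusted p 7.16e-06, and adjusted p = 0.386 with an estimated correlation), with CYP1B1 at 4.41 ± 0.26, UGT1A6 at 4.39 ± 0.16, CYP1A2 at 2.84 ± 0.25 and AHRR at 2.67 ± 0.40. With IND, 20 of 23 NRF2 targets rose and 0 fell (adjusted p 1.18e-08, and adjusted p = 0.206 with an estimated correlation), with SRXN1 at 3.30 ± 0.03, OSGIN1 at 3.07 ± 0.03 and haem oxygenase (HMOX1) at least 12.7-fold higher. With IND, 19 of 21 cholesterol synthesis genes fell and 0 rose (adjusted p 3.05e-08, and adjusted p = 0.223 with an estimated correlation). With IND, 12 of 14 fatty acid synthesis genes fell and 0 rose (adjusted p 1.04e-05, and adjusted p = 0.254 with an estimated correlation), with SCD at -2.38 ± 0.06. With IND, 21 of 25 secreted protein genes fell and 0 rose (adjusted p 1.22e-08, and adjusted p = 0.287 with an estimated correlation), with APOB at -2.60 ± 0.01. With IND, 30 of 30 G2 and mitosis genes fell and 0 rose (adjusted p 2.93e-13, and adjusted p = 0.189 with an estimated correlation), with TOP2A at -2.60 ± 0.05. With IND, 25 of 26 DNA replication genes fell and 0 rose (adjusted p 6.33e-11, and adjusted p = 0.254 with an estimated correlation), with MCM2 at -1.84 ± 0.01. With IND, 11 of 20 DNA repair genes fell and 2 rose (adjusted p 0.00126, and adjusted p = 0.284 with an estimated correlation). With IND, 13 of 30 p53 targets rose and 1 fell (adjusted p 0.00425, and adjusted p = 0.579 with an estimated correlation), with CDKN1A at 2.38 ± 0.03 and TP53I3 at 1.48 ± 0.07. With IND, 9 of 14 histone genes rose and 1 fell (adjusted p 0.00107, and adjusted p = 0.413 with an estimated correlation), with H1-2 at 2.46 ± 0.10.

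**Figure D2:**
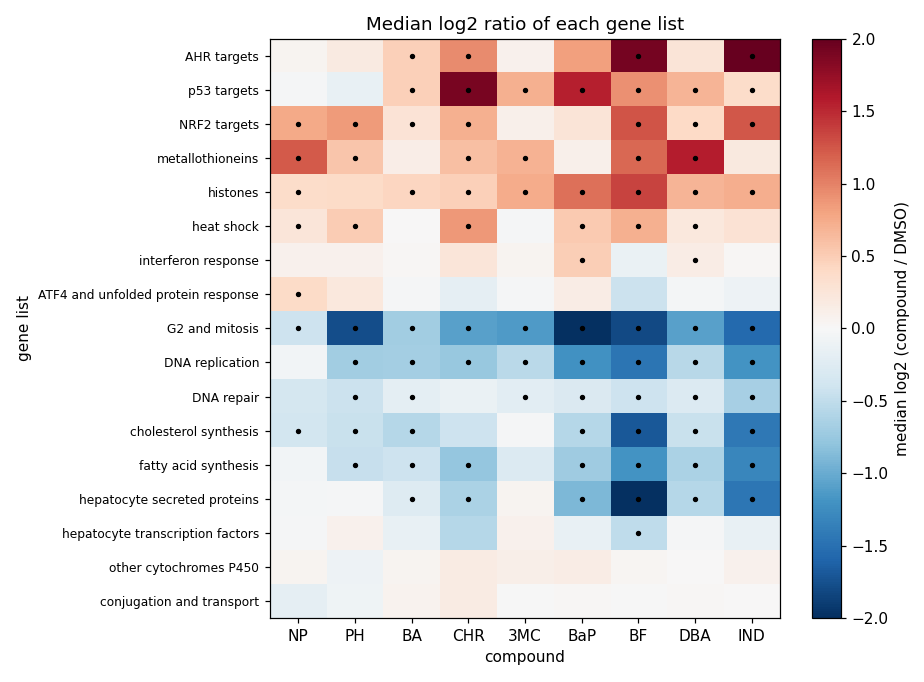
Median log2 ratio of compound over DMSO (colour) of 17 gene lists (vertical axis) for each compound (horizontal axis). Dots mark lists with a camera adjusted p under 0.05 at the preset correlation. With an estimated correlation 0 of 345 tests passed, or 64 without BA array 1. With median centring the secreted proteins in DBA and BA turned upwards.

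DBA raised CYP1A1 by 3.45 ± 0.24, the metal-binding protein MT2A by 2.89 ± 0.28, the stress cytokine GDF15 by 2.69 ± 0.41, TIMP1 by 2.57 ± 0.15 and RGS10 by 2.24 ± 0.40. Among the lowest ratios were those of the chromatin protein HMGB2 (-2.85 ± 0.15), SLC22A3 (-2.24 ± 0.04, with -0.34 on another probe), NDC80 (-2.22 ± 0.20) and SLCO4C1 (-2.13 ± 0.02). In all, 1784 genes changed, of which 1252 fell, or 1602 higher and 647 lower with median centring, and 3423 changed with plain background subtraction. Other probes of genes that changed 2-fold had a median of 0.336 times the ratio of the probe used. With DBA, 20 of 30 p53 targets rose and 1 fell (adjusted p 3.71e-13, and adjusted p = 0.223 with an estimated correlation), with TP53I3 at 2.14 ± 0.22 and DDB2 at 1.57 ± 0.10. With DBA, 7 of 17 AHR targets rose and 2 fell, which did not pass (adjusted p 0.0598). With DBA, 6 of 9 genes of the metallothionein list rose and 1 fell (adjusted p 2.79e-06, and adjusted p = 0.0806 with an estimated correlation), with MT1X at 1.63 ± 0.17. With DBA, 8 of 23 NRF2 targets rose and 0 fell (adjusted p 6.91e-05, and adjusted p = 0.386 with an estimated correlation), with AKR1B10 at 1.64 ± 0.14. With DBA, 9 of 15 histone genes rose and 1 fell (adjusted p 4.76e-08, and adjusted p = 0.189 with an estimated correlation), with H1-2 at 1.97 ± 0.16. With DBA, 26 of 30 G2 and mitosis genes fell and 0 rose (adjusted p 1.07e-19, and adjusted p = 0.189 with an estimated correlation), with CDK1 at -2.08 ± 0.10 and HMMR at -2.04 ± 0.09. With DBA, 12 of 27 DNA replication genes fell and 1 rose (adjusted p 2.21e-06, and adjusted p = 0.416 with an estimated correlation), with RRM1 at -1.24 ± 0.09. With DBA, 5 of 20 DNA repair genes fell and 0 rose (adjusted p 0.0157, and adjusted p = 0.223 with an estimated correlation), with MSH6 at -1.03 ± 0.04. With DBA, 9 of 22 cholesterol synthesis genes fell and 0 rose (adjusted p 0.00309, and adjusted p = 0.670 with an estimated correlation). With DBA, 9 of 14 fatty acid synthesis genes fell and 1 rose (adjusted p 0.00570, and adjusted p = 0.589 with an estimated correlation), with GPAM at -1.23 ± 0.07. With DBA, 12 of 25 secreted protein genes fell and 3 rose (adjusted p 0.0157, and adjusted p = 0.571 with an estimated correlation), with HP at -1.45 ± 0.04 and AMBP at 1.26 ± 0.13, a list whose test turned upwards with median centring. With DBA, 5 of 18 interferon response genes rose and 0 fell (adjusted p 0.0191, and adjusted p = 0.189 with an estimated correlation), with ISG15 at 1.3 ± 0.10. With DBA, 3 of 12 heat shock genes rose and 1 fell (adjusted p 0.00356, and adjusted p = 0.189 with an estimated correlation), with HSPB1 at 1.32 ± 0.13.

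3MC raised CYP1A1 by 2.90 ± 0.02, IGFBP1, which binds insulin-like growth factors, by 2.60 ± 0.24, the phospholipid transfer protein PLTP by 2.51 ± 0.08, LCN15 by 2.49 ± 0.09 and GDF15 by 2.11 ± 0.14. Ratios were lowest in the complement regulator CD46 (-3.38 ± 0.06, with 0.20 and 0.18 on other probes), NDC80 (-2.20 ± 0.26), UGT2A3 (-2.19 ± 0.07), UHRF1, which maintains DNA methylation (-2.14 ± 0.06), and HMGB2 (-2.12 ± 0.05). In all, 636 genes rose and 1288 fell. Other probes of genes that changed 2-fold had a median of 0.172 times the ratio of the probe used. With 3MC, 19 of 30 p53 targets rose and 1 fell (adjusted p 2.68e-10, and adjusted p = 0.282 with an estimated correlation), with TP53I3 at 1.98 ± 0.09 and PHLDA3 at 1.73 ± 0.04. With 3MC, 2 of 17 AHR targets rose and 2 fell, or 3 and 2 adjusted over the list alone, and the list did not pass (adjusted p 0.650). With 3MC, 26 of 30 G2 and mitosis genes fell and 0 rose (adjusted p 3.14e-19, and adjusted p = 0.189 with an estimated correlation), with CDK1 at -2.02 ± 0.09 and HMMR at -1.95 ± 0.10. With 3MC, 13 of 27 DNA replication genes fell and 0 rose (adjusted p 3.81e-07, and adjusted p = 0.382 with an estimated correlation), with MCM6 at -1.12 ± 0.06. With 3MC, 7 of 20 DNA repair genes fell and 2 rose (adjusted p 0.0447, and adjusted p = 0.284 with an estimated correlation), with BRCA1 at -1.2 ± 0.03. With 3MC, 10 of 15 histone genes rose and 1 fell (adjusted p 1.58e-05, and adjusted p = 0.254 with an estimated correlation), with H2BC5 at 1.27 ± 0.04. With 3MC, 6 of 9 genes of the metallothionein list rose and 1 fell (adjusted p 0.00160, and adjusted p = 0.189 with an estimated correlation), with MT2A at 1.67 ± 0.09.

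NP left CYP1A1 at 0.47 ± 0.05, short of 1.5-fold. TIMP1 rose by 2.83 ± 0.04, GDF15 by 2.39 ± 0.16, PHLDA2 by 2.38 ± 0.14, MT2A by 2.38 ± 0.11 and the matrix protease MMP3 by 2.29 ± 0.02. The lowest ratios were in CD46 (-3.89 ± 0.11, with -0.04 and 0.13 on other probes), ITM2B (-2.85 ± 0.02), LRRC40 (-2.70 ± 0.06), BTN2A1 (-2.62 ± 0.06) and BAG4 (-2.59 ± 0.08, with -0.45 on another probe). In all, 1161 genes rose and 2171 fell, or 614 higher and 2989 lower with median centring. Other probes of genes that changed 2-fold had a median of 0.120 times the ratio of the probe used, and 67.9% had its sign. With NP, 13 of 23 NRF2 targets rose and 1 fell (adjusted p 0.00147, and adjusted p = 0.511 with an estimated correlation), with SRXN1 at 1.81 ± 0.06 and TXNRD1 at 1.5 ± 0.08. With NP, 5 of 9 genes of the metallothionein list rose and 0 fell (adjusted p 9.55e-04, and adjusted p = 0.189 with an estimated correlation), with MT1B at 1.39 ± 0.16. With NP, 4 of 22 genes of ATF4 and the unfolded protein response rose and 1 fell (adjusted p 0.0124, and adjusted p = 0.189 with an estimated correlation), with DDIT4 at 1.14 ± 0.06 and DDIT3 at 0.70 ± 0.06. With NP, 2 of 12 heat shock genes rose and 0 fell (adjusted p 0.0234, and adjusted p = 0.257 with an estimated correlation), with HSPA6 at 1.84 ± 0.15. With NP, 6 of 15 histone genes rose and 0 fell (adjusted p 0.0302, and adjusted p = 0.579 with an estimated correlation), with H2BC4 at 1.46 ± 0.02. With NP, 11 of 30 G2 and mitosis genes fell and 0 rose (adjusted p 1.74e-04, and adjusted p = 0.579 with an estimated correlation), with HMMR at -1.44 ± 0.03 and CDK1 at -1.33 ± 0.04. With NP, 7 of 22 cholesterol synthesis genes fell and 1 rose (adjusted p 0.00674, and adjusted p = 0.712 with an estimated correlation), with SQLE at -1.57 ± 0.06. With NP, 5 of 30 p53 targets fell and 4 rose, with a median of -0.02, a mean of 0.03 and a test that pointed downwards without passing (adjusted p 0.956). PLK3 was at 1.32 ± 0.05 and FAS at -1.13 ± 0.10. With NP, 4 of 17 AHR targets fell and 1 rose, with a median of 0.06, a mean of -0.13 and a test that pointed downwards without passing (adjusted p 0.782). NQO1 was at -0.62 ± 0.05 and SERPINB2 at -0.73 ± 0.09, with 0.06 on another probe.

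PH raised DUSP5, a phosphatase of ERK kinases, by 4.18 ± 0.10, TIMP1 by 3.62 ± 0.18, the cytochrome P450 CYP2S1 by 3.29 ± 0.12 and the filament protein NES by 3.25 ± 0.14. CYP1A1 rose by 2.63 ± 0.28. Ratios were lowest in the kinesin KIF20A (-2.60 ± 0.10), NDC80 (-2.44 ± 0.03), CHST9 (-2.41 ± 0.12), PLPPR1 (-2.38 ± 0.13) and MAGEE2 (-2.36 ± 0.21). In all, 1833 genes rose and 1363 fell. With PH, 30 of 30 G2 and mitosis genes fell and 0 rose (adjusted p 1.91e-21, and adjusted p = 0.189 with an estimated correlation), with TOP2A at -2.29 ± 0.05 and TTK at -2.17 ± 0.13. With PH, 15 of 27 DNA replication genes fell and 0 rose (adjusted p 8.04e-08, and adjusted p = 0.352 with an estimated correlation), with MCM2 at -1.28 ± 0.17. With PH, 9 of 20 DNA repair genes fell and 2 rose (adjusted p 0.00545, and adjusted p = 0.189 with an estimated correlation), with OGG1 at 1.36 ± 0.16 and RAD51C at -1.11 ± 0.07. With PH, 15 of 23 NRF2 targets rose and 0 fell (adjusted p 1.74e-05, and adjusted p = 0.352 with an estimated correlation), with SRXN1 at 1.90 ± 0.14 and GCLC at 1.69 ± 0.13. With PH, 6 of 12 heat shock genes rose and 0 fell (adjusted p 0.00688, and adjusted p = 0.206 with an estimated correlation), with HSPH1 at 1.13 ± 0.07. With PH, 4 of 9 genes of the metallothionein list rose and 1 fell (adjusted p 0.0302, and adjusted p = 0.263 with an estimated correlation), with MT2A at least 4.60-fold higher. With PH, 9 of 22 cholesterol synthesis genes fell and 1 rose (adjusted p 0.0226, and adjusted p = 0.785 with an estimated correlation). With PH, 5 of 14 fatty acid synthesis genes fell and 0 rose (adjusted p 0.0113, and adjusted p = 0.633 with an estimated correlation), with ELOVL6 at -0.97 ± 0.03. With PH, 8 of 30 p53 targets fell and 7 rose, with a median of -0.15, a mean of 0.10 and a test that pointed downwards without passing (adjusted p 0.482). PLK3 was at 2.81 ± 0.04, CDKN1A at 1.54 ± 0.20 and SESN1 at -1.02 ± 0.05. With PH, 4 of 17 AHR targets rose and 0 fell, and the list did not pass (adjusted p 0.325).

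BA raised IGFBP1 by 2.33 ± 1.60, VSIR, a checkpoint receptor of immune cells, by 1.80 ± 1.39, AGR2 by 1.74 ± 1.39, DUSP5 by 1.72 ± 1.42 and IGFBP3 by 1.70 ± 1.22. The lowest ratios were in GPC6 (-2.17 ± 1.73), MLIP (-1.91 ± 1.57), OSBP2 (-1.83 ± 1.25), ANGPTL8 (-1.76 ± 1.12) and DPYD, which breaks down uracil (-1.75 ± 1.36, with 0.27 and -1.74 on other probes). Array 1 stood apart. CYP1A1 was at 0.58 on array 1 and at 6.25 and 6.23 on arrays 2 and 3, where Cy5 was saturated. In all, 353 genes rose and 536 fell. Without array 1 there were 782 and 1026, and 0 genes passed in limma on the BA arrays alone, with 4017 at an unadjusted p under 0.05. With median centring 2267 genes changed. Without array 1, a choice for these values made after seeing the data, IGFBP1 was at 3.25 ± 0.11 (SE), DUSP5 at 2.54 ± 0.06, ALDH3A1 at 1.56 ± 0.09, SRXN1 at 1.28 ± 0.07, SCD at -1.80 ± 0.07, GPC6 at -3.17 ± 0.08, MLIP at -2.81 ± 0.08, OSBP2 at -2.54 ± 0.09, ANGPTL8 at -2.40 ± 0.05 and DPYD at -2.54 ± 0.10. With BA, 8 of 17 AHR targets rose and 0 fell (adjusted p 9.49e-04, and adjusted p = 0.312 with an estimated correlation), with ALDH3A1 at 1.01 ± 0.96. With BA, 8 of 30 p53 targets rose and 0 fell (adjusted p 2.77e-09, and adjusted p = 0.293 with an estimated correlation), with CDKN1A at 1.40 ± 1.1, and without array 1, 20 rose and 0 fell. With BA, 20 of 30 G2 and mitosis genes fell and 0 rose (adjusted p 3.14e-19, and adjusted p = 0.189 with an estimated correlation), with CDK1 at -1.06 ± 0.09. With BA, 15 of 27 DNA replication genes fell and 0 rose (adjusted p 2.92e-14, and adjusted p = 0.206 with an estimated correlation), with MCM6 at -1.21 ± 0.27. With BA, 4 of 20 DNA repair genes fell and 1 rose (adjusted p 0.00122, and adjusted p = 0.189 with an estimated correlation), and without array 1, 2 rose and 5 fell. With BA, 5 of 23 NRF2 targets rose and 0 fell (adjusted p 0.00338, and adjusted p = 0.560 with an estimated correlation), with SRXN1 at 0.83 ± 0.77, and without array 1, 10 rose and 0 fell. With BA, 5 of 15 histone genes rose and 1 fell (adjusted p 2.84e-04, and adjusted p = 0.312 with an estimated correlation), with H1-2 at 1.45 ± 0.83. With BA, 10 of 22 cholesterol synthesis genes fell and 0 rose (adjusted p 1.02e-04, and adjusted p = 0.578 with an estimated correlation). With BA, 4 of 14 fatty acid synthesis genes fell and 0 rose (adjusted p 1.25e-04, and adjusted p = 0.451 with an estimated correlation), with SCD at -1.17 ± 1.11. Without array 1, 0 rose and 15 fell in the first list and 0 rose and 9 fell in the second. With BA, 4 of 25 secreted protein genes fell and 0 rose (adjusted p 0.00196, and adjusted p = 0.440 with an estimated correlation), with AFP at -0.93 ± 0.74, a list that turned upwards with median centring, and without array 1, 0 rose and 9 fell. With BA, 4 of 20 TGF-beta, adhesion and matrix genes rose and 0 fell (adjusted p 0.0472, and adjusted p = 0.254 with an estimated correlation), and the list did not pass without array 1 (adjusted p 0.0680). Hepatocyte transcription factors passed in that setting alone (adjusted p 0.0307), where with an estimated correlation the lists that passed were AHR targets (0.00650), p53 targets (0.00906), G2 and mitosis (0.00906), DNA replication (4.86e-04), cholesterol synthesis (4.86e-04), fatty acid synthesis (0.00128) and secreted proteins (0.0270), adjusted p in brackets.

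For AHR targets, 7 genes were tested in all 28 pairs of the 8 compounds that share a platform. Of 196 differences 143 passed at an adjusted p under 0.05 alone, 124 of them 1.5-fold or more. Leaving out BA array 1, these were 163 and 132. Across layouts, layout and compound cannot be told apart. CYP1A1 (gene 1543, GRCh38 chromosome 15, 74719542 to 74725528) did not pass between BaP and CHR, with a difference of -0.11 (95% interval -1.88 to 1.67, adjusted p 0.920), nor between BaP and BF, with -0.53 (95% interval -2.30 to 1.24, adjusted p 0.579). Cy5 of this spot was saturated on 2 CHR arrays, 3 BF arrays and BA arrays 2 and 3. These levels are lower bounds and cannot be ranked. BA array 1 enters the error that all pairs share. Without it BaP minus BF was -0.53 (adjusted p 0.00564). This does not rank them, as BaP was as bright (mean log2 intensity 12.9, BF 12.7) and the DMSO sets differ. DBA minus BA (adjusted p 0.351) and 3MC minus BA (adjusted p 0.132) did not pass with all arrays. Without BA array 1 they were -2.79 and -3.34. These are not bounds, as background correction moves ratios on dim arrays (CYP1A2 with DBA 0.66, or 2.13 with plain subtraction). NP was lower than PH across layouts, with a difference of -2.16 (95% interval -3.93 to -0.39, adjusted p 0.0275). CYP1B1 (gene 1545, chromosome 2, 38067509 to 38076151) rose by 6.4 ± 0.28 with BF, whose DMSO signal stood above background on 1 of 3 arrays, 2.55 ± 0.10 with BaP and 1.58 ± 0.16 with CHR, and was at 0.18 ± 0.03 with DBA and 0.02 ± 0.04 with 3MC. With that dim DMSO signal BaP minus BF was no higher than -3.86 (adjusted p 6.58e-12). BaP minus CHR was 0.96 (95% interval 0.45 to 1.47, adjusted p 0.00154), while NP minus PH was -0.16 (95% interval -0.67 to 0.35, adjusted p 0.572). AHRR, the repressor of the AHR (gene 57491, chromosome 5, 321714 to 438285), rose by 4.11 ± 0.11 with BF, 1.96 ± 0.05 with CHR, 1.75 ± 0.17 with BaP and 0.89 ± 0.17 with DBA. BaP minus BF was -2.36 (95% interval -2.75 to -1.96, adjusted p 3.86e-10), and CHR minus BA 1.37 (95% interval 0.98 to 1.77, adjusted p 1.60e-06). The quinone reductase NQO1 rose by 1.11 ± 0.02 with BF, 0.94 ± 0.15 with CHR and 0.63 ± 0.05 with DBA and fell by 0.62 ± 0.05 with NP on the log2 scale. It was at -0.34 ± 0.20 with BaP and -0.50 ± 0.06 with 3MC, and DBA minus 3MC was 1.13 (95% interval 0.93 to 1.32, adjusted p 8.22e-10). TIPARP rose by 1.91 ± 0.04 with BF, 0.71 ± 0.22 with CHR and 0.70 ± 0.13 with BaP, and BaP minus CHR was -0.0029 (95% interval -0.20 to 0.19, adjusted p 0.986). ALDH3A1 rose by 3.33 ± 0.28 with CHR, 3.11 ± 0.10 with BF, 1.63 ± 0.09 with BaP and 1.2 ± 0.17 with DBA. CYP1A2 rose by 1.48 ± 0.05 with BaP and at least 3.50-fold with CHR. With DBA it passed as at least 1.58-fold, and changed sign with plain background subtraction and with quantile scaling, where another probe stood for the gene. That probe had 0.54 with BaP, 0.60 with CHR and -0.18 with DBA. For other members of the list, 10 of 17 genes rose and 0 fell with BaP, without the list passing (adjusted p 0.0599). With BaP UGT1A6 was at 2.77 ± 0.13, CYP2S1 at 2.47 ± 0.14, IGFBP1 at 2.68 ± 0.18 and SLC7A5 at 0.82 ± 0.03, the last changing sign with the mean of its probes. With BF STC2 was at 1.62 ± 0.14, SERPINB2 at 2.71 ± 1.00 (5.91 on another probe) and NFE2L2 at 0.90 ± 0.06, which also changed sign with the mean of its probes. STC2 was at -1.68 ± 0.11 with 3MC and -1.18 ± 0.14 with DBA, but another probe had 0.26 and 0.42.

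**Figure D3:**
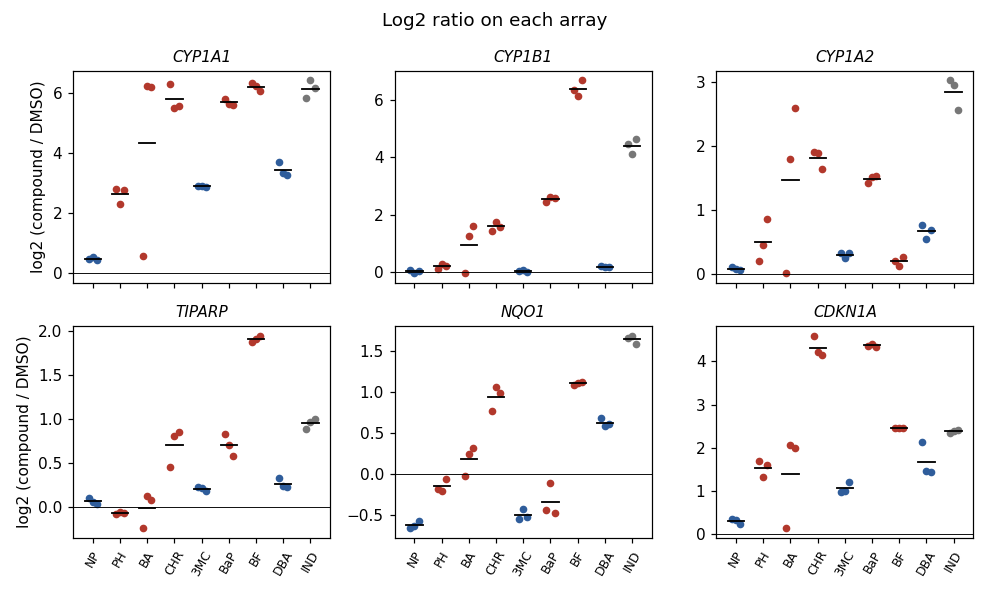
Log2 ratio of compound over DMSO on each array (points) with the mean of 3 arrays (lines) for the genes named above each panel. For BA, array 1 lies apart, with CYP1A1 at 0.58.

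**Figure D4:**
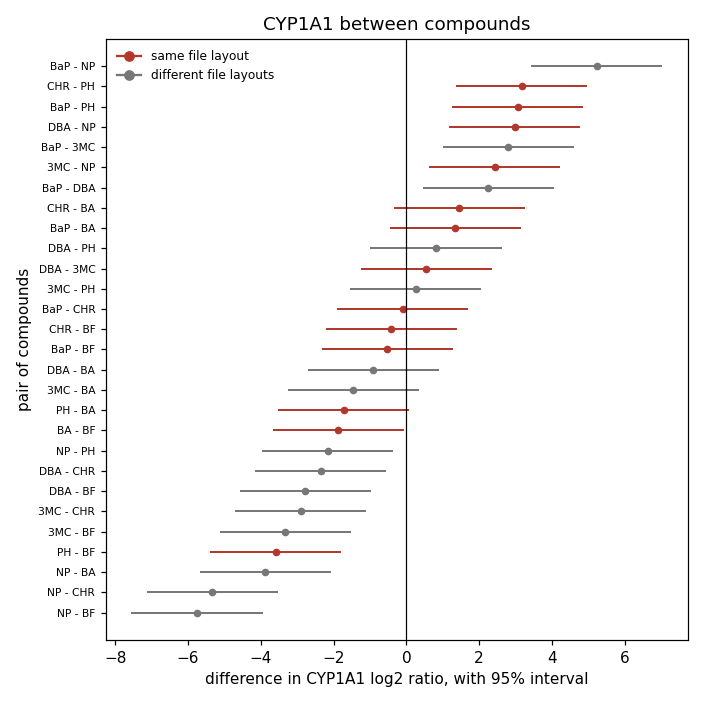
Difference in the CYP1A1 log2 ratio (points) with its 95% interval (lines) for the 28 pairs of compounds that share a platform, 3 arrays each and BA array 1 included. Pairs with CHR, BF or BA rest on saturated spots. Colour tells pairs on arrays of the same file layout from pairs on different layouts.

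The 6 larger compounds of the shared platform (BaP, DBA, 3MC, CHR, BA and BF) were compared with NP and PH, which have fewer rings. Differences in log2 ratio are given ± SE. Higher with the larger compounds were SULF2 (2.79 ± 0.08), FAS (2.71 ± 0.14), IGFBP7 (2.38 ± 0.05), GASK1B (2.22 ± 0.07), FDXR (2.04 ± 0.10), UBD (2.02 ± 0.05), DEPP1 (1.89 ± 0.10), TIGAR (1.75 ± 0.09), RPS27L (1.75 ± 0.09) and PCNA (1.70 ± 0.04). FAS, FDXR, TIGAR and RPS27L are known p53 targets. Lower were ANGPTL8 (-2.34 ± 0.17), ITPR3 (-2.07 ± 0.04), FGFR4 (-1.84 ± 0.13), KCTD15 (-1.70 ± 0.05), MYBL2 (-1.67 ± 0.13), ASS1 (-1.67 ± 0.07), CEBPA (-1.66 ± 0.14), KCNMB3 (-1.64 ± 0.03), DDIT4 (-1.63 ± 0.07) and AHSG (-1.60 ± 0.10). ASS1 and AHSG are hepatocyte genes. Spots of FDXR and AHSG were saturated on some arrays, so their values are approximate. In all, 1118 genes were higher and 1316 lower, or 2454 higher and 786 lower with median centring. Both file layouts hold larger and smaller compounds, so the difference was also taken within each, a choice made after seeing the data. DBA and 3MC against NP gave 1563 genes and BaP, CHR, BA and BF against PH 3682, of which 912 and 2062 were among those of the joint comparison, in the same direction. With layout as a block 1782 genes passed, and with the 3 sets alike in the DMSO channel as a block 1803. The set of CHR, BA and BF holds no smaller compound, so this second block compares only BaP with PH and DBA and 3MC with NP. Within layouts and with blocks, lists were tested at the preset correlation alone. In these layouts SULF2 was at 3.23 and 2.29, FAS at 2.18 and 2.90, IGFBP7 at 2.75 and 2.14, PCNA at 1.39 and 1.91 and MYBL2 at -0.39 and -2.39, the first MYBL2 value short of the threshold (adjusted p 0.131). The genes named as lower were all nearer to 0 on the dimmer arrays, with FGFR4 at -0.70 and -2.41, KCNMB3 at -0.69 and -2.53, ASS1 at -0.75 and -2.21, CEBPA at -0.70 and -2.22, KCTD15 at -1.22 and -1.96, ANGPTL8 at -1.68 and -2.31, ITPR3 at -1.74 and -2.35, AHSG at -1.23 and -1.67 and DDIT4 at -1.32 and -1.61. Here 20 of 30 p53 targets were higher and 1 lower (adjusted p 7.73e-10, and adjusted p = 0.284 with an estimated correlation), with TP53I3 at 2.31 ± 0.15, and the list passed in both layouts (adjusted p 1.18e-09 and 1.85e-09). Here 10 of 17 AHR targets were higher and 1 lower (adjusted p 0.00217, and adjusted p = 0.364 with an estimated correlation). CYP1A1 was at 3.18 ± 0.49, approximate because of saturated and dim spots. In the layouts the list's adjusted p was 0.0434 and 0.0207. With the DMSO sets as a block, so without CHR, BA and BF, this list did not pass (adjusted p 0.0799). Here 8 of 22 genes of ATF4 and the unfolded protein response were lower and 0 higher (adjusted p 0.00104, and adjusted p = 0.0918 with an estimated correlation), with TRIB3 at -1.03 ± 0.12, and the adjusted p in the layouts was 0.00128 and 0.00448. Here 13 of 27 DNA replication genes were lower and 2 higher (adjusted p 9.19e-05, and adjusted p = 0.511 with an estimated correlation), with MCM5 at -1.42 ± 0.07, and both layouts were down (adjusted p 2.85e-06 and 0.0318). Here 8 of 30 G2 and mitosis genes were lower and 1 higher (adjusted p 1.87e-04, and adjusted p = 0.579 with an estimated correlation), with CDC20 at -1.25 ± 0.06, and the direction turned between layouts, down on the dimmer arrays (adjusted p 1.79e-14) and up on the others without passing (adjusted p 0.240). With the DMSO sets as a block, 27 genes were lower and 0 higher (adjusted p 1.32e-15), and in BaP minus PH, of 1 layout and 1 DMSO set, 27 genes were lower and 1 higher (adjusted p 8.44e-13). Here 8 of 25 secreted protein genes were lower and 0 higher (adjusted p 1.11e-04, and adjusted p = 0.312 with an estimated correlation), with HP at -1.71 ± 0.08, and they passed on the brighter arrays (adjusted p 6.86e-06) and not on the dimmer (adjusted p 0.773), with 5 lower and 0 higher in the DMSO-set block (adjusted p 5.28e-04). Here 5 of 15 histone genes were higher and 1 lower (adjusted p 0.00653, and adjusted p = 0.466 with an estimated correlation), with H1-2 at 1.70 ± 0.13, and the adjusted p in the layouts was 0.0649 and 0.00185, with 8 higher and 0 lower in the DMSO-set block (adjusted p 0.00137). Fatty acid synthesis passed too without BA array 1 (4 lower and 0 higher, adjusted p 0.00331), but with all arrays in neither layout nor block (adjusted p 0.119 to 0.490). With an estimated correlation AHR targets (adjusted p 0.0122), p53 targets (0.0135) and ATF4 and the unfolded protein response (0.0122) passed without that array. So did DNA replication (0.00650), fatty acid synthesis (0.0237) and secreted proteins (0.0218). Some lists passed only in parts of this comparison. NRF2 targets were lower on the dimmer arrays (8 lower and 2 higher, adjusted p 0.00261), in the DMSO-set block (5 lower and 0 higher, adjusted p 0.00128) and in BaP minus PH (6 lower and 0 higher, adjusted p 0.00812). Interferon response genes were higher in the DMSO-set block (7 higher and 1 lower, adjusted p 0.0293) and in BaP minus PH (7 higher and 1 lower, adjusted p 0.0178), and in the same fits metallothioneins were lower (2 lower and 1 higher, adjusted p 0.0431, and 4 lower and 1 higher, adjusted p 0.0265). Hepatocyte transcription factors were lower on the brighter arrays (7 lower and 1 higher, adjusted p 0.0289). AHR targets and the ATF4 list did not pass in BaP minus PH (adjusted p 0.265 and 0.187).

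DBA has a further fused ring beside BA. In DBA minus BA, MLIP (1.97 ± 0.41) was higher, and HMGB2 (-1.97 ± 0.19), DEPP1 (-1.86 ± 0.17) and SMPDL3A (-1.85 ± 0.09) lower. Cy5 of ALDOA and MT2A was saturated on 3 BA arrays, so their differences, at most 1.80 and 1.76, do not show that they were higher with DBA. When BA array 1 was left out, MLIP was at 2.88 ± 0.10, HMGB2 at -1.57 ± 0.07, DEPP1 at -2.20 ± 0.08 and SMPDL3A at -1.98 ± 0.07. In all, 677 genes were higher and 1183 lower, or 1781 higher and 1176 lower with median centring and 2577 in all without BA array 1. The compounds were on arrays of different layouts, so layout and compound cannot be told apart here. With DBA 6 of 9 genes of the metallothionein list were higher and 0 lower (adjusted p 3.18e-07, and adjusted p = 0.0785 with an estimated correlation), with MT1B at 1.51 ± 0.09 and MT2A counted although it is an upper bound. With DBA 11 of 30 G2 and mitosis genes were lower and 0 higher (adjusted p 2.46e-04, and adjusted p = 0.579 with an estimated correlation), with HMMR at -1.72 ± 0.08. With DBA 5 of 15 histone genes were higher and 0 lower (adjusted p 9.11e-04, and adjusted p = 0.362 with an estimated correlation), with H2BC4 at 0.88 ± 0.10. With DBA 2 of 18 interferon response genes were higher and 0 lower (adjusted p 0.00688, and adjusted p = 0.189 with an estimated correlation), with ISG15 at 1.11 ± 0.09. With DBA 6 of 30 p53 targets were higher and 1 lower (adjusted p 0.00713, and adjusted p = 0.676 with an estimated correlation), with DDB2 at 1.07 ± 0.14. With DBA 2 of 12 heat shock genes were higher and 1 lower (adjusted p 0.0191, and adjusted p = 0.254 with an estimated correlation). Neither list passed without BA array 1 (adjusted p 0.474 and 0.0595). AHR targets did not pass with all arrays (adjusted p 0.701). Without BA array 1 the G2 and mitosis list had 7 lower and 3 higher, adjusted p 0.0376, and further lists passed, which were AHR targets (8 lower and 1 higher, adjusted p 0.0116), TGF-beta, adhesion and matrix (7 lower and 0 higher, adjusted p 0.0400), DNA replication (8 higher and 1 lower, adjusted p 0.00170), cholesterol synthesis (7 higher and 2 lower, adjusted p 0.00422) and fatty acid synthesis (3 higher and 0 lower, adjusted p 0.0432). With an estimated correlation, DNA replication (adjusted p 0.0350), cholesterol synthesis (0.0194) and metallothioneins (0.00906) then passed.

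In 3MC minus BA, PLTP (2.15 ± 0.11), LCN15 (2.09 ± 0.14) and the proteoglycan GPC1 (1.88 ± 0.11) were higher, and CD46 (-3.05 ± 0.08), RFPL1 (-2.36 ± 0.16) and the secreted phosphoprotein SPP1 (-2.33 ± 0.18) lower. Other probes of CD46 pointed the other way, at 0.20 and 0.18 with 3MC and -0.41 and -0.43 with BA. With BA array 1 left out, PLTP was at 1.98 ± 0.08, LCN15 at 1.82 ± 0.08, GPC1 at 1.83 ± 0.13, CD46 at -3.06 ± 0.08, RFPL1 at -2.49 ± 0.17 and SPP1 at -2.72 ± 0.06. In all, 884 genes were higher and 1353 lower, 2953 in all without BA array 1 and 3381 with median centring. Here too the layout and the compound cannot be told apart. With 3MC 15 of 30 G2 and mitosis genes were lower and 0 higher (adjusted p 5.28e-05, and adjusted p = 0.560 with an estimated correlation), with HMMR at -1.64 ± 0.08. With 3MC 3 of 9 genes of the metallothionein list were higher and 0 lower, or 4 and 0 adjusted over the list alone (adjusted p 0.00206, and adjusted p = 0.189 with an estimated correlation), with MT1E at 0.72 ± 0.08. With 3MC 6 of 30 p53 targets were higher and 1 lower (adjusted p 0.0377, and adjusted p = 0.785 with an estimated correlation), with PHLDA3 at 1.36 ± 0.16 and a median that turned negative with median centring. With 3MC 2 of 15 histone genes were higher and 1 lower (adjusted p 0.0285, and adjusted p = 0.578 with an estimated correlation). AHR targets did not pass with all arrays (adjusted p 0.110). Without BA array 1 the p53 and histone lists did not pass (adjusted p 0.886 and 0.370), and the G2 and mitosis list had 10 lower and 2 higher, adjusted p 0.0142. Further lists then passed, which were AHR targets (11 lower and 0 higher, adjusted p 2.71e-04), NRF2 targets (10 lower and 0 higher, adjusted p 0.0114), cholesterol synthesis (13 higher and 1 lower, adjusted p 1.22e-06), fatty acid synthesis (5 higher and 0 lower, adjusted p 5.38e-04), secreted proteins (12 higher and 2 lower, adjusted p 0.00958), hepatocyte transcription factors (4 higher and 0 lower, adjusted p 0.00958) and DNA replication (7 higher and 1 lower, adjusted p 0.0114). With an estimated correlation, AHR targets (adjusted p 0.0133), cholesterol synthesis (0.00168) and fatty acid synthesis (0.0106) then passed.

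CHR and BA are isomers on arrays of the same layout. In CHR minus BA, ZNF385A (3.83 ± 0.09), PROCR (3.25 ± 0.29) and the receptor HCAR3 (3.21 ± 0.18) were higher, and the glucose transporter SLC2A2 (-2.85 ± 0.11) and NBEA (-2.29 ± 0.22) lower. Against BA arrays 2 and 3 alone these were 3.71 ± 0.08, 2.64 ± 0.10, 2.84 ± 0.08, -3.03 ± 0.07 and -1.81 ± 0.08. In all, 1603 genes were higher and 1622 lower, or 1583 and 1493 without BA array 1. With CHR 25 of 30 p53 targets were higher and 0 lower (adjusted p 3.30e-13, and adjusted p = 0.223 with an estimated correlation), with TP53I3 at 2.98 ± 0.27 and BTG2 at 2.39 ± 0.13. With CHR 8 of 12 heat shock genes were higher and 0 lower (adjusted p 1.54e-05, and adjusted p = 0.0918 with an estimated correlation), with HSPB1 at 1.70 ± 0.07. With CHR 9 of 23 NRF2 targets were higher and 1 lower (adjusted p 0.00578, and adjusted p = 0.579 with an estimated correlation), with AKR1B10 at 1.76 ± 0.25. With CHR 4 of 9 genes of the metallothionein list were higher and 1 lower (adjusted p 0.00257, and adjusted p = 0.189 with an estimated correlation), with MT1F at -1.02 ± 0.38. With CHR 6 of 18 interferon response genes were higher and 2 lower (adjusted p 0.0223, and adjusted p = 0.189 with an estimated correlation), with OAS1 at 1.25 ± 0.07. With CHR 11 of 30 G2 and mitosis genes were lower and 1 higher (adjusted p 8.24e-04, and adjusted p = 0.632 with an estimated correlation), with PLK1 at -1.54 ± 0.14 and PTTG1 at 1.32 ± 0.07. AHR targets did not pass (adjusted p 0.384). With BA array 1 left out, the lists had 6 lower and 1 higher, adjusted p 0.00581 in G2 and mitosis, 7 higher and 2 lower, adjusted p 0.0288 in NRF2 targets and 6 higher and 0 lower, adjusted p 0.00105 in metallothioneins, where MT1F was at -0.28 ± 0.21, short of the threshold. Cholesterol synthesis then passed (8 higher and 1 lower, adjusted p 5.83e-04). With an estimated correlation, p53 targets (adjusted p 0.00650) and cholesterol synthesis (0.00826) then passed.

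BaP and BF are isomers too, on arrays of the same layout but with DMSO channels of different sets. In BaP minus BF, VNN2 (5.94 ± 0.15), LYPLA2 (5.15 ± 0.15) and CTSD (5.0 ± 0.18) were higher, and SLC16A6 (-4.50 ± 0.30), the iron hormone HAMP (-3.91 ± 0.07) and RAMP1 (-3.29 ± 0.18) lower. The DMSO channel of CTSD stood at percentile 96.2 of genes on the BF arrays and 49.5 on the BaP arrays, that of VNN2 at 71.6 and 43.5, and that of LYPLA2 at 74.2 and 42.0. In all, 3770 genes were higher and 2328 lower. With BaP 11 of 17 AHR targets were lower and 2 higher (adjusted p 0.00186, and adjusted p = 0.359 with an estimated correlation). With BaP 13 of 23 NRF2 targets were lower and 2 higher (adjusted p 0.00352, and adjusted p = 0.560 with an estimated correlation), with AKR1B10 at -2.75 ± 0.25. With BaP 17 of 30 p53 targets were higher and 2 lower (adjusted p 7.09e-04, and adjusted p = 0.579 with an estimated correlation), with TP53I3 at 2.32 ± 0.27. With BaP 22 of 30 G2 and mitosis genes were lower and 0 higher (adjusted p 9.12e-09, and adjusted p = 0.374 with an estimated correlation), with ASPM at -2.06 ± 0.10. With BaP 19 of 25 secreted protein genes were higher and 1 lower (adjusted p 1.11e-04, and adjusted p = 0.312 with an estimated correlation), with VTN at 2.06 ± 0.16. With BaP 16 of 22 cholesterol synthesis genes were higher and 0 lower (adjusted p 0.00688, and adjusted p = 0.712 with an estimated correlation), with NSDHL at 1.68 ± 0.13. With BaP 8 of 9 genes of the metallothionein list were lower and 1 higher (adjusted p 0.00186, and adjusted p = 0.189 with an estimated correlation), with MT1F at -1.49 ± 0.38. With BaP 7 of 18 interferon response genes were higher and 2 lower (adjusted p 0.0381, and adjusted p = 0.193 with an estimated correlation), with IFI27 at 2.69 ± 0.16.

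PH has a further fused ring beside NP. In PH minus NP, CD46 (3.59 ± 0.08), BTN2A1 (3.00 ± 0.12) and CYP2S1 (2.97 ± 0.22) were higher, and KIF20A (-2.47 ± 0.11), IRAG2 (-2.36 ± 0.12) and RACGAP1P1 (-2.30 ± 0.10) lower. Other probes of CD46 pointed the other way, at -0.59 and -0.65 with PH and -0.04 and 0.13 with NP. In all, 2617 genes were higher and 1412 lower, or 3632 higher and 1060 lower with median centring, and the layout and the compound cannot be told apart. With PH 28 of 30 G2 and mitosis genes were lower and 0 higher (adjusted p 3.19e-17, and adjusted p = 0.206 with an estimated correlation), with BUB1B at -1.95 ± 0.08. With PH 13 of 27 DNA replication genes were lower and 0 higher (adjusted p 7.75e-06, and adjusted p = 0.448 with an estimated correlation), with MCM2 at -1.74 ± 0.15. With PH 2 of 9 genes of the metallothionein list were lower and 0 higher (adjusted p 0.0446, and adjusted p = 0.284 with an estimated correlation), with MT1B at -0.77 ± 0.09. The p53 targets had a median of -0.05, a mean of 0.07 and a test that pointed downwards without passing (adjusted p 0.700), and AHR targets did not pass (adjusted p 0.270).

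Among the 8 compounds of the shared platform, 15509 of 17269 genes differed by limma's F test at an adjusted p under 0.05. The lists of fatty acid oxidation (lowest adjusted p 0.268), other cytochromes P450 (0.105), conjugation and transport (0.134), inflammation and the acute phase (0.212) and hypoxia and glycolysis (0.169) passed in 0 of the 15 comparisons. Markers of other cell types did not pass either (lowest adjusted p 0.0950), with at most 6 of 18 genes higher against DMSO. Nor did reference genes such as ACTB and GAPDH (lowest adjusted p 0.109), of which BF raised 2 and lowered 3 of 14.

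**Figure D5:**
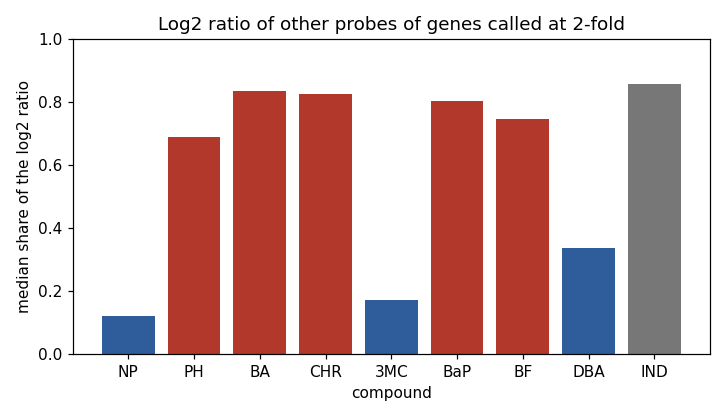
Median ratio of the log2 value of other probes of a gene to that of the probe used (bars), over genes that changed 2-fold against DMSO, for each compound. It was 0.120 for NP, 0.172 for 3MC and 0.336 for DBA, and 0.689 to 0.857 for the others. Other probes are dimmer by rule.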

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

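The test of this part was chosen only after the arrays had shown 2 file layouts. In 3456 genes the difference between larger and smaller compounds itself differed between the layouts by limma's interaction contrast at an adjusted p under 0.05 and 1.5-fold. It was higher on the dimmer arrays (DBA and 3MC minus NP) than on the brighter ones (BaP, CHR, BA and BF minus PH) in 2222 of them and lower in 1234, so a difference between groups brought this result here. As lists, G2 and mitosis genes (20 of 30 lower, adjusted p 9.56e-11) and p53 targets (9 of 30 lower, adjusted p 0.00189) had a lower difference on the dimmer arrays. Genes for secreted proteins (15 of 25 higher, adjusted p 1.61e-05), cholesterol synthesis (10 of 22, adjusted p 0.00833) and hepatocyte transcription factors (6 of 15, adjusted p 0.00833) had a higher one. BaP minus PH, of 1 layout and 1 DMSO set, had a G2 and mitosis median of -1.40, under the -0.67 of the dimmer arrays and far from the 0.18 of the brighter ones together, so the result for this list depends on the compounds and DMSO sets taken. AHR targets did not pass (adjusted p 0.306), and these lists were tested at the preset correlation alone. Each layout holds other compounds, so layout and compound cannot be told apart in this result, and no biological explanation was tested.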

How the results depend on the processing

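The comparisons within layouts, with a layout or DMSO-set block, and without BA array 1 in every count and list were chosen after seeing the data. Of the alternative values of the counts, 303 lay within 1.5 times the reported one and 63 did not. Over 43 settings, the 724 named gene results kept direction and side of the threshold 11516 times, passed it anew 25 times, lost it 198 times (63 of them when each comparison was fitted on its own arrays) and reversed 8 times. Replicate block, quantile scaling, no background correction, the mean of a gene's probes and no dim-probe filter left every count within 1.5 times. The counts outside are given below by setting. With plain background subtraction they were 3423 for DBA, 1580 for BA, 3688 for DBA minus BA and 3357 for 3MC minus BA. With median centring they were 2267 for BA, 2957 for DBA minus BA and 3381 for 3MC minus BA. Array weights gave 1764 for BA, and leaving out spots not found 9613 for the F test among compounds. Where both channels had to stand above background on every array, 8196 genes were left to test, and the counts were 2663 for BaP, 2361 for CHR, 2017 for PH, 412 for BA and 3745 for BF. For differences they were 1563 for the larger compounds minus NP and PH, 1762 for CHR minus BA, 3601 for BaP minus BF, 2510 for PH minus NP, 1458 for 3MC minus BA, 8168 for the F test among compounds and 24 for the AHR pairs. The authors' log2 values, which hold fewer arrays, gave 2679 for CHR, 318 for BA, 2051 for CHR minus BA, 9109 for the F test among compounds and 83 for the AHR pairs, and moved the median of all genes by 0.12 in BF. On its own arrays BA had 0 genes in limma, with 4017 at an unadjusted p under 0.05. For the larger compounds minus NP and PH, 1563 passed on the dimmer arrays and 3682 on the brighter. The number that passed with the adjusted p alone, and then with 2-fold, moves by construction. It was 10954 and 1867 for BaP, 7005 and 460 for DBA, 8430 and 482 for 3MC, 10073 and 1074 for NP, 11600 and 1556 for CHR, 11119 and 955 for PH, 8188 and 156 for BA and 12351 and 3162 for BF. It was also 10580 and 1319 for IND, 11174 and 534 for the larger compounds minus NP and PH, 7354 and 342 for DBA minus BA, 9405 and 931 for CHR minus BA, 11062 and 2999 for BaP minus BF, 10097 and 1325 for PH minus NP and 8160 and 438 for 3MC minus BA. Of the 345 list tests camera called 121 at the preset correlation, 0 with an estimated one (60 at an unadjusted p under 0.05), and fry 276. With median centring it called 122, of which 101 were shared in direction, and 2 turned. Without BA array 1 it called 139, and 64 with an estimated correlation, so the latter outcome depends on this array. Reversed genes were CYP1A2 with DBA, at -0.22 with plain subtraction and -0.18 with quantile scaling, and DPYD with BA, at 0.27 without spots not found. In the CYP1A2 and DPYD values another probe had become the brightest and stood for the gene, while the probe used otherwise had 2.13, 0.66 and -1.76. With the mean of a gene's probes SLC7A5 was at -0.027 with BaP, MT1G at -0.14 with CHR and -0.015 with BF, and NFE2L2 at -0.25 with PH and -0.68 with BF. Apart from this and from the fewer genes or arrays named here, the cause was not tested. Leaving out each array in turn, the counts ranged over 588 to 1808 for BA, with the highest without array 1, and 4294 to 4403 for BaP, 1681 to 1864 for DBA, 1925 to 1957 for 3MC, 3302 to 3381 for NP, 4031 to 4516 for CHR, 3164 to 3315 for PH, 6225 to 6342 for BF and 3409 to 3494 for IND. For differences they were 2396 to 2530 for the larger compounds minus NP and PH, 1762 to 2577 for DBA minus BA, 3017 to 3700 for CHR minus BA, 6030 to 6144 for BaP minus BF, 3982 to 4111 for PH minus NP, 2100 to 2953 for 3MC minus BA, 15297 to 16027 for the F test among compounds and 137 to 163 for the AHR pairs. IND minus BF was not run because their platforms differ, a block of scan date or slide because the files give neither, and a replicate block of IND because it leaves no residual degrees of freedom. Spots not above background limit what dim genes can show.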

Other observations

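In this part, the tests of exchanged labels, of noise and of cell cycle genes on BA array 1 were chosen only after the result was seen. Compounds shared many of the genes they changed. DBA and 3MC both raised 336 genes and both lowered 834, and their log2 ratios correlated at 0.83 across genes. Independent lists would share 19.6 and 93.4. Their DMSO channels are of 1 set, and how much a shared DMSO RNA adds to this correlation was not tested. The correlation simulated for unchanged compounds against 1 shared DMSO RNA averaged 0.750. That value follows from the spreads assumed and not from the data, so it cannot serve as a reference. BaP and CHR both raised 1265 and lowered 976 (independent lists 306 and 213), at 0.69, and CHR and BF 1095 and 1486 (independent lists 325 and 433), at 0.61. NP and CHR both raised 204 and lowered 256 (independent lists 136 and 267), at -0.04. Genes are not independent replicates, and compounds whose DMSO channels were alike share any part that comes from the DMSO RNA.

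Over 413 genes that changed 2-fold on both BA arrays 2 and 3, the median ratio was 1.28 on those arrays and 0.0847 on array 1, a share of 0.0660, while on arrays of the other compounds the same share was 0.931 to 1.09. An exchange with another array of the platform is argued against, since 0 arrays of other compounds lay closer to BA arrays 2 and 3 than to their own compound. RNA of untreated cells in both channels stays open. The small share restates the pattern and cannot support this over another cause of small ratios, and over 57 genes of G2 and mitosis and DNA replication the median was -0.28 on array 1 and -0.89 on the others, a share of 0.312 between the bounds of 0.25 and 0.5 set for and against it, with CDK1 at -0.99 on array 1. Noise stays open as a part, since the spread of genes near 0 was 1.67 times that on arrays 2 and 3, over the bound of 1.5 set for noise, but those genes were chosen for small ratios on arrays 2 and 3. The Cy5 signal of CYP1A1 stood at percentile 45.5 on array 1 and 100 on the others, and no biological explanation was tested, as the design gives none.

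The DMSO channels of the CHR and BA arrays differed from those of the BaP and PH arrays by 4-fold or more in 864 genes, with a median difference of 2.63. Over these genes the median BF ratio was 1.05 toward the BaP and PH level, a share of 0.400, beside 0.18 for CHR and 0.03 for BA. BF RNA from cells like those behind the DMSO channel of the BaP and PH arrays would give a share of 0.5 or more, which was not reached, and the share also lay above the bound set against it. A response to BF itself stays open and was not tested, and neither can be told apart from the other in these genes, since BF has no other DMSO channel.

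NP and 3MC shared 273 genes that rose and 983 that fell, with a correlation of 0.74 across genes. A bias of dim spots is argued against, since over the brighter genes with plain subtraction the correlation was 0.737. Chance values shared through a common DMSO RNA stay open. The covariance was 0.139 and the highest of 100 simulated ones 0.0241. The simulation (mean correlation 0.750) used the spread between arrays of a compound. That spread does not hold a deviation of 1 shared DMSO RNA, so the simulation cannot decide. Effects of single probes stay open. Over 273 genes that changed 2-fold the same way in both, 198 other probes had a median of 0.104 times the NP ratio of the probe used, beside 0.785 for genes shared by BaP and CHR. The probe used is its gene's brightest, so others are dimmer, which may lower their ratios on these arrays and was not tested. A response that both compounds share stays open and was not tested apart from the probes.

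Other splits of the arrays were set beside the counts. For the F test among compounds, 1 of 100 splits of the 24 arrays gave a count as large, the real one of 15509. The highest other was 2920, so arrays of a compound were more alike than arrays grouped at random. Chance between cultures or batches is not excluded by this, since the arrays of a compound may be technical repeats. For the larger compounds against NP and PH, 2 of 100 splits of the arrays into 18 and 6 gave a count as large, the real one included. The real split had 1633 genes in a model of both groups, and the highest other had more, 2472. Such splits break up the arrays of a compound, which are alike, so they do not exclude chance. When whole compounds were regrouped, 7 of 28 choices of a pair of compounds gave as many as the real 2434, so chance cannot be excluded at that level. CHR with BF gave 4559, and NP with 3MC, which share a layout and a DMSO set, 3124, and with layout as a block the real count was 1782. For pairs, 10 splits are too few for a share under 0.05. The real and the highest other counts were 1860 and 437 for DBA minus BA, 3225 and 264 for CHR minus BA, 2237 and 454 for 3MC minus BA, 6098 and 0 for BaP minus BF, and 4029 and 0 for PH minus NP.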
